A study of Mus musculus with 2 samples.

How the data were processed

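RNA was measured in 2 pools of mouse morulae, the stage of compacted cells that precedes the blastocyst. Per the labels, the embryos were of the ICR strain and had been injected with double-stranded RNA against Nat10 (dsNat10) or against GFP (dsGFP), a sequence foreign to the mouse that served as control. The design text speaks of 50 injected morulae, and whether that number is per library is not given in the sources used here. There was 1 library per group, so no difference has a replicate check.

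Per the labels, polyadenylated RNA was made into libraries by the SMART-seq2 protocol, which amplifies full-length cDNA from small amounts of RNA by PCR, and was sequenced with paired ends on a DNBSEQ instrument. Per the submitters' processing notes, reads were trimmed with Trim Galore, mapped to the GRCm38 genome with HISAT and counted per gene with HTSeq, and versions and the annotation release are not given in the sources used here. The deposited table holds 12836 genes with 3 kinds of values for each library. The deposited estimated counts are not normalized, and 23.2% of genes have a fractional estimated count in at least 1 library. HTSeq with its usual settings gives whole numbers, so the program that made the fractional values is not given in the sources used here. The authors also deposited FPKM values, which divide by gene length and by the library's total, and TPM values, which sum to 1000000 in each library. No per-sample column of the table was left unused.

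Estimated counts were rounded to whole numbers. They summed to 28303119 reads in the dsNat10 library and 29139232 reads in the dsGFP library. Counts were expressed as CPM, reads per 1000000 reads, with TMM scaling from edgeR 4.0.16 in R 4.3.3, which moved the log2 CPM ratio, before any pseudocount, by -0.03 against plain totals. The log2 ratio is log2 of dsNat10 CPM plus 1 over dsGFP CPM plus 1, which understates the difference of low genes. A gene was called higher or lower by the size rule when its mean CPM was 5 or more, its log2 ratio was at least 1 in size, and the exact (Clopper-Pearson) 95% interval of the ratio of counts excluded equality. Folds printed with an interval are plain CPM ratios with no pseudocount. For a gene at 0 in 1 library the fold is a bound against a floor of 3 counts in that library, which is 0.105 CPM in dsNat10 and 0.104 CPM in dsGFP. Intervals and floors cover only the counting error of reads taken as independent draws. PCR reads without molecular identifiers are not independent molecules, so the intervals are too narrow for a count of molecules. No p-value was computed.

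Genes with fractional counts are reported as uncertain, since their reads could be split with a near-identical copy or an overlapping gene. The kit does not mark strand, so reads of overlapping antisense genes cannot be told apart. Entrez identifiers of 12800 of the 12836 genes matched the RefSeq gene table of GRCm38.p6, the build the submitters name, from which coordinates were taken. Transcript lengths came from the longest protein-coding transcript in GENCODE M21 and were found for 97.1% of the genes that passed the mean filter.

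The genes named in the text were chosen by a rule fixed before the data were examined. The rule takes Nat10, Nop2, the 12 highest and 12 lowest genes by log2 ratio that met the size rule with a mean CPM of 20 or more (leaving out predicted genes, Rik clones and pseudogenes), and from each gene list up to 4 members with the largest log2 ratio in size plus the most abundant member. The 12 highest and 12 lowest genes with a mean CPM of 100 or more were added after seeing the data. In the same way, 32 gene lists were fixed before the data were examined, and 29 had at least 3 members passing the mean filter. For each, the median log2 ratio was placed among 10000 random lists of the same size drawn from genes in the same of 20 bins of mean CPM. The percentile describes these 2 libraries and tests nothing about the treatment. A list of genes encoded by the mitochondrial genome was not analysed here, and a few genes that these rules name are not reported here, though they count in the list totals.

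The size rule and its interval were checked on simulated Poisson counts for the comparison of dsNat10 with dsGFP over 8738 genes. The rule recovered 96.0% of genes with a simulated fold of 4 and 96.0% of those with a fold of 3, called 0.0% of unchanged genes, and the interval held the true ratio for 95.2% of genes. The list percentile was checked on the measured log2 ratios, with lists drawn at random from the same genes. Of these lists, 2.0% fell outside the central 95%. A list of 30 such genes, shifted by 0.5 on the log2 scale, reached percentile 97.6. Such draws come from the pool that the percentile itself uses, so they check the computation only. The simulated counts hold no variation between embryos or in amplification, so they say nothing about those.

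Alternatives fixed before the data were examined were plain totals, DESeq2 1.42.0 size factors, totals without the 50 most abundant genes, pseudocounts of 0.1 and 5, other filters on the mean, other fold thresholds, a stricter interval and none, the deeper library thinned to the depth of the other, and other ways of matching random lists. Alternatives added after seeing the data were a mean CPM of 50 or more, genes above 0 in both libraries, the deposited TPM and FPKM values, matching on transcript length, and list medians with genes at 0 set to their bound. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.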

Results

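Gene expression was compared between 1 library from mouse morulae injected with double-stranded RNA against Nat10 and 1 library from morulae injected with double-stranded RNA against GFP. The libraries held 28303119 and 29139232 estimated reads over 12836 genes. The series concerns N4-acetylcytidine, an RNA modification that the enzyme Nat10 writes, its presence on the mRNA of Nop2, and the passage of the embryo from morula to blastocyst. With 1 library per group, the differences below have no replicate check, and each describes these libraries.

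The target of the injected RNA was far lower in the dsNat10 library. Nat10 (Entrez gene 98956, GRCm38 chromosome 2, 103721258 to 103762954) had 37 reads in dsNat10 and 886 in dsGFP, a 23.7-fold lower level (95% counting interval 17.1 to 33.9) that left 4.22% of the control level (2.95% to 5.86%). Nop2 (Entrez gene 110109, chromosome 6, 125131883 to 125144753), which encodes an RNA cytosine methyltransferase of the nucleolus, had 5787 reads against 8365, or 1.43-fold lower, with 69.9% of the control level remaining (67.6% to 72.3%). Its log2 ratio of -0.51 is short of the size rule. Ratios as low were also found among other genes of like abundance. Counting the gene itself, 82 of 1065 genes within 1.25-fold of the dsGFP level of Nat10 had a ratio as low as that of Nat10 (7.70%). In the same way, 73 of 430 genes near the level of Nop2 had one as low as that of Nop2 (17.0%).

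Across the 8738 genes with a mean CPM of 5 or more, 1330 were higher and 1334 lower in dsNat10 by the size rule. The calls lay mostly among genes of low abundance. At a mean CPM of 50 or more, a limit chosen after seeing the data, 167 genes were higher and 164 lower. The spread of log2 ratios, as the scaled median absolute deviation, was 2.26 for genes with a mean of 5 to 10 CPM and 0.38 for genes with 200 CPM or more. After rounding, 2657 genes were at 0 in dsNat10 and 458 at 0 in dsGFP. Of the genes called lower, 313 were at 0 in dsNat10, and of those called higher, 102 were at 0 in dsGFP. Among genes with at least 100 and under 300 reads in dsGFP, 31.0% were at 0 in dsNat10, while 8.41% were at 0 in dsGFP among genes with as many reads in dsNat10. With at least 300 and under 1000 reads in the other library, these shares were 10.2% and 3.43%. Anxa6, Wwc1, Marveld2, Polk and Herpud1, named below at 0 in dsNat10, have dsGFP reads in that range. Their bounds do not cover such common zeros.

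**Figure D1:**
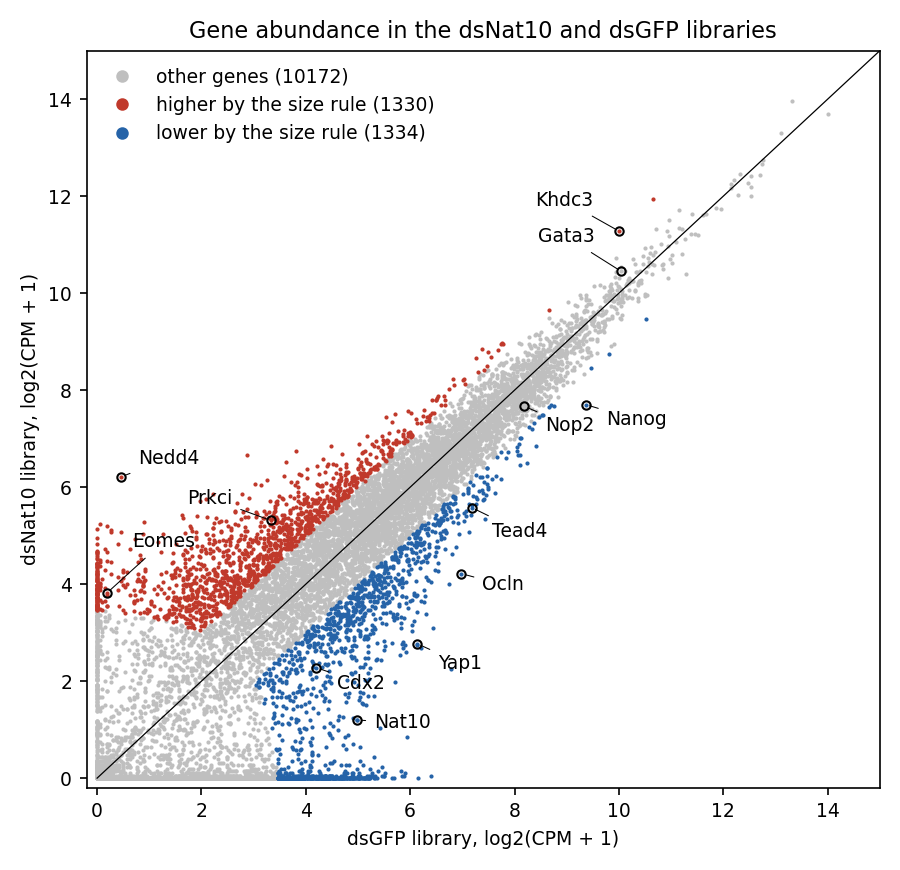
Each point is a gene, with log2(CPM + 1) in the dsGFP library on the x axis and in the dsNat10 library on the y axis, and colours mark the 1330 genes higher and 1334 genes lower by the size rule. The points spread widely at low abundance and close in on the line of equal abundance at high abundance, and Nat10 lies far below that line.

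**Figure D2:**
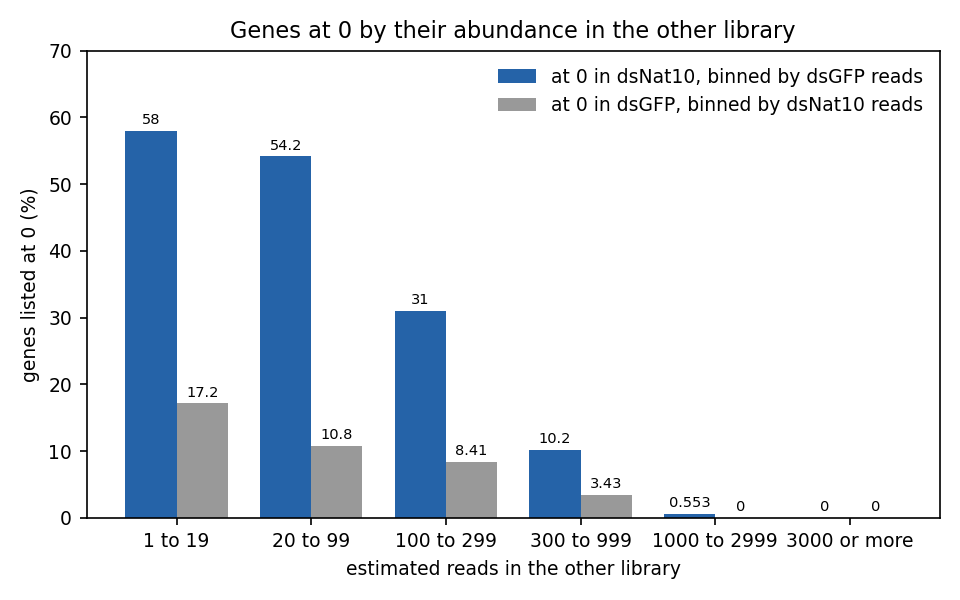
Bars give the percentage of genes listed at 0 in a library, binned by the estimated reads of the same genes in the other library. At 100 reads or more and under 300, 31.0% of genes were at 0 in dsNat10 and 8.41% at 0 in dsGFP, and no gene with 3000 reads or more in the other library was at 0 in either.

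The lowest genes by the naming rule were nearly undetected in dsNat10. Rbsn, a protein of early endosomes, had 0 reads against 2022 and was at least 667-fold lower. Arnt, a partner of the hypoxia-inducible and dioxin-receptor transcription factors, had 0 against 1455 (at least 480-fold lower), and Atp9a, a membrane ATPase, had 0 against 1420 (at least 468-fold lower). Ddx46, a helicase of the spliceosome, had 1 read against 1680, a ratio of 1663-fold with a counting interval of 298 to 65718. Prdm10, Sprtn, Arpc1a, Flot2, Hs1bp3 and Dcp1a had 1 to 3 reads in dsNat10 against 1244 to 1696 in dsGFP, and Nkiras2 and Dalrd3 were as low but have fractional counts and are uncertain. At the other end stood Nedd4, a ubiquitin ligase, with 2096 reads against 11, 193-fold higher (107 to 386). Mrm1, a methyltransferase of mitochondrial rRNA, was 15.9-fold higher (13.7 to 18.6), and Myo1a, Mapre3, Acsbg1, Rhbdf1, Mpzl1, Rfx2 and Brpf3 were between 9.26-fold and 20.2-fold higher. Sfi1, Myo1e and Malt1 complete the highest genes, with fractional counts.

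Among genes with a mean of 100 CPM or more, where no gene is at 0, the differences were smaller. Nono, a nuclear RNA-binding protein, was 3.38-fold lower (3.23 to 3.53), Eftud2, a GTPase of the spliceosome, 3.16-fold lower (3.02 to 3.30), the DNA repair scaffold Xrcc1 3.01-fold lower (2.86 to 3.16), and the glucose transporter Slc2a1 3.09-fold lower (2.91 to 3.28). Manf, Knop1, Sapcd2 and Rbmxl1 were also lower, and so were Plp2, Rbpj, Nanog and Rnf167, whose counts are fractional. Higher were Rflnb (3.84-fold, 3.61 to 4.08), the semaphorin receptor Plxnb2 (3.50-fold, 3.31 to 3.71) and Asb13 (3.08-fold, 2.92 to 3.26). Polr2m, Tex264, Anp32b and Tnpo2 were between 2.53-fold and 2.67-fold higher, and Xpo4, Asf1a, Dvl3 and Clpb were higher with fractional counts.

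Genes of the trophectoderm, the outer lineage that forms the blastocyst wall, differed in both directions. Of 17 members, 6 were lower and 2 higher by the size rule, and the median log2 ratio was -0.22, at percentile 12.3 of matched random lists. At a mean of 50 CPM or more the median was 0.07, at percentile 75.0. Cdx2, a transcription factor of this lineage, had 110 reads against 502 and was 4.52-fold lower (3.67 to 5.60). Tinagl1 was 7.10-fold lower (6.26 to 8.08), and Anxa6 had 0 reads against 368, at least 121-fold lower. Tead4 (3.07-fold, 2.89 to 3.27), Krt8 (2.10-fold, 2.05 to 2.14) and Id2 (2.76-fold, 2.37 to 3.23), named after their values were seen, complete the lower members. Eomes had 374 reads against 4, 94.5-fold higher (36.6 to 349), and Tspan8, also named afterwards, was 2.73-fold higher (2.45 to 3.06). The most abundant member, Gata3, was 1.33-fold higher (1.31 to 1.35), short of the size rule.

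Of 23 genes of pluripotency and the inner cell mass, 20 were within the size limit, 2 were lower and 1 was higher, with a median of 0.04 at percentile 69.2. Klf17 was 3.49-fold higher (3.13 to 3.89) and Klf4 2.61-fold lower (2.25 to 3.04). Nanog had 5928 reads against 18966, or 3.17-fold lower (3.08 to 3.26), but its counts are fractional and its value is uncertain. Nr5a2 was 1.91-fold higher (1.82 to 2.02) and the abundant Dppa5a, also fractional, 1.07-fold higher. Among 9 genes of the primitive endoderm, 3 were higher and 0 lower, with Sparc 4.63-fold higher (3.43 to 6.36) and Pdgfra 2.95-fold higher (2.45 to 3.56). That list's median was 0.49, at percentile 87.7, and became -0.32 when all 12 members in the table were counted with those at 0 at their bound. It was also below 0 at a mean of 20 CPM or more (-0.41), in TPM (-0.23) and in FPKM (-0.34).

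The Hippo pathway, which in the morula separates outer from inner cells, had 5 members higher and 5 lower of 20, with a median of -0.11 at percentile 26.2. Yap1, a transcriptional co-activator at the end of the pathway, had 167 reads against 1992 and was 11.8-fold lower (10.1 to 13.9). Amot, a junctional protein that binds it, was 3.44-fold lower (2.99 to 3.96), and Wwc1 had 0 reads against 554, at least 183-fold lower. Ajuba was 22.8-fold higher (16.6 to 32.2), with 904 reads against 40. Wwtr1, the paralogue of Yap1, was 2.73-fold higher (2.56 to 2.91), Lats2, a kinase of the pathway, 2.58-fold higher (2.23 to 2.98), and Ccn2, a known target gene of Yap1, 3.35-fold lower (2.86 to 3.95), all 3 named after their values were seen. Nf2, the most abundant member, was 1.08-fold lower (1.03 to 1.13), but higher in TPM and FPKM.

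Genes for cavitation and tight junctions, needed for the seal and the fluid transport of the blastocyst wall, had a low median that depends on the processing. Of 17 members, 6 were lower and 0 higher, and the median of -0.42 lay at percentile 1.22. Ocln had 503 reads against 3612, 7.11-fold lower (6.47 to 7.82). Tjp1 was 3.45-fold lower (3.11 to 3.84), Tjp3 2.76-fold lower (2.42 to 3.16), and Marveld2 had 0 reads against 631, at least 208-fold lower. The abundant claudin Cldn4 had 33847 reads against 33055, 1.03-fold higher (1.02 to 1.05). The list lay inside the central 95% of random lists at a mean of 20 CPM or more (percentile 9.82), at 50 CPM or more (median -0.17, percentile 18.6), in TPM (4.66), in FPKM (15.6) and without matching on expression (3.12). Of 23 genes for adhesion and polarity, 3 were higher and 3 lower (median -0.09, percentile 28.5, and 0.13 at a mean of 20 CPM or more), with Prkci 4.29-fold higher (3.74 to 4.93), Rac1 2.51-fold higher (2.26 to 2.80), Scrib 3.60-fold lower and Llgl1 2.91-fold lower (2.67 to 3.18).

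**Figure D3:**
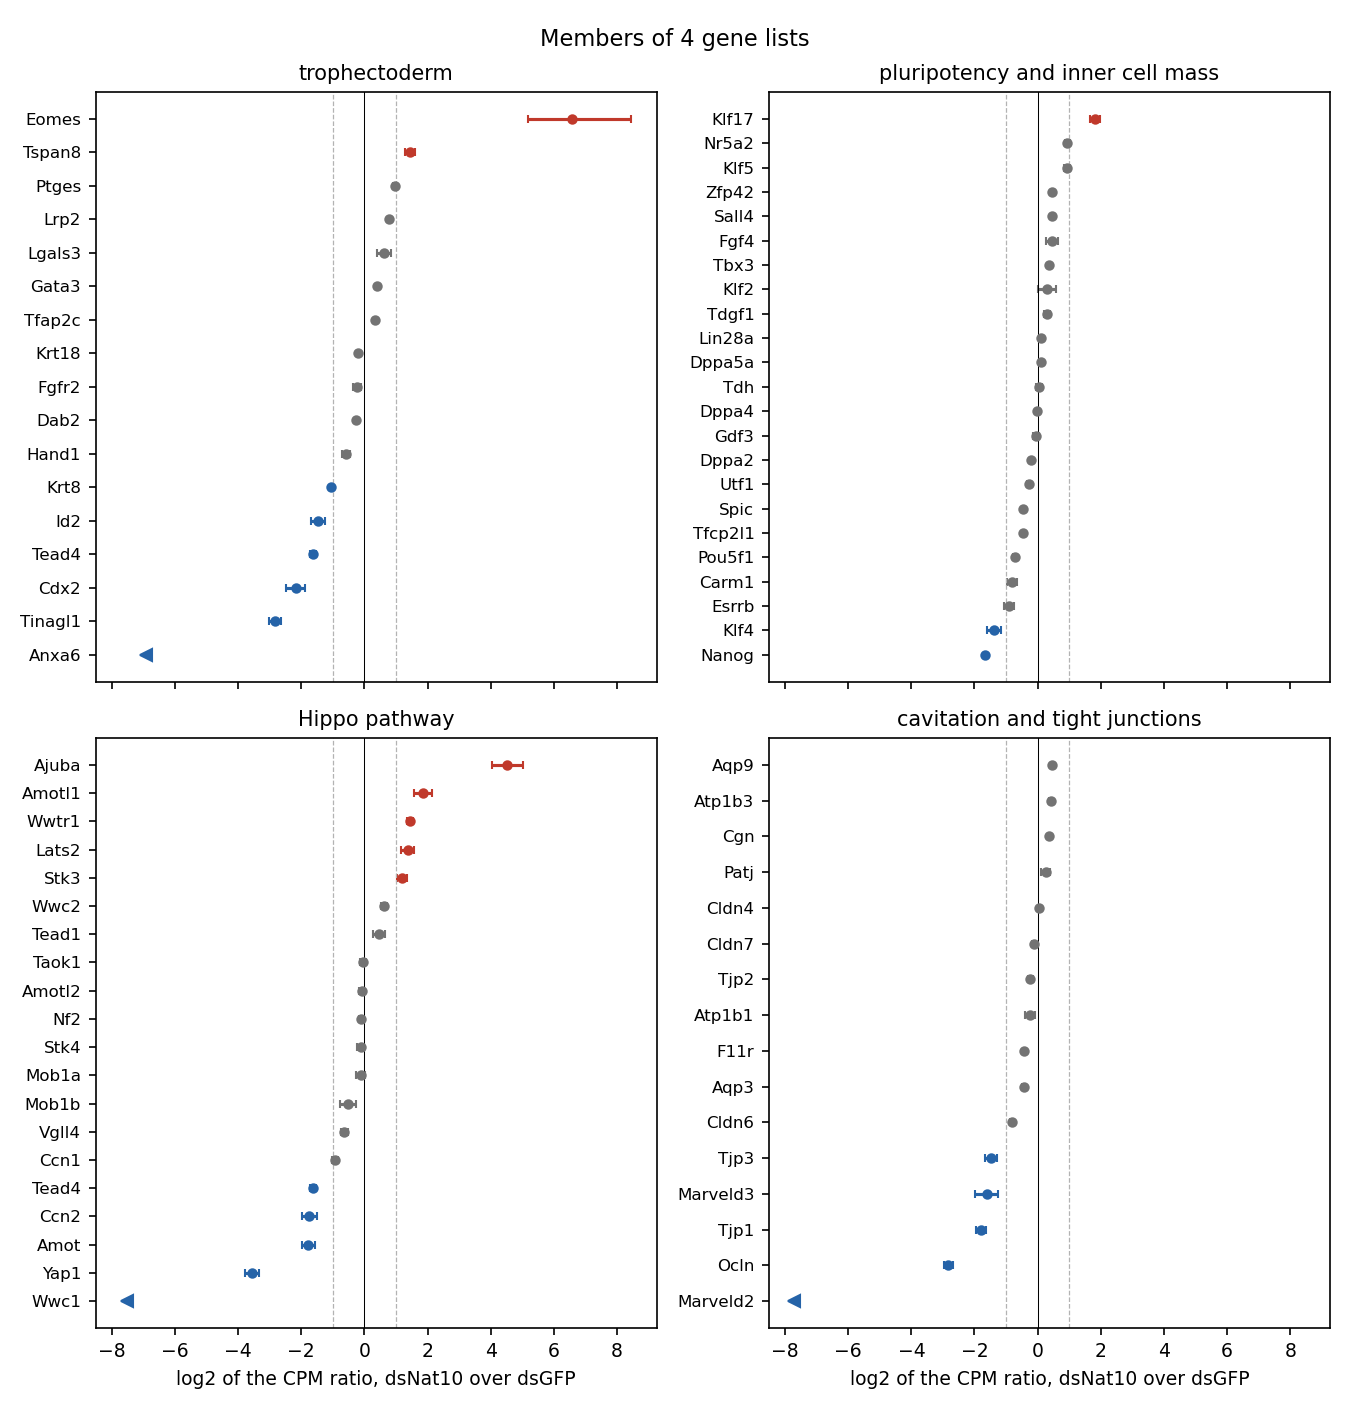
Rows are genes of 4 lists with a mean CPM of 5 or more, the x axis gives log2 of their CPM ratio of dsNat10 over dsGFP, bars are 95% counting intervals, and triangles are bounds for genes at 0 in 1 library. Red and blue mark genes higher and lower by the size rule, with 5 higher and 5 lower of 20 in the Hippo pathway.

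Most genes of the proteasome and of the large ribosomal subunit had ratios below 0, by small amounts. Of 31 proteasome genes, 25 had a ratio below 0 and none met the size rule, and the median of -0.25 lay at percentile 0.315. Psmd6 was 1.84-fold lower (1.78 to 1.90), Psma5 1.75-fold lower (1.72 to 1.79) and Psmb6 had 33763 reads against 33992. Of 48 proteins of the large ribosomal subunit, 40 had a ratio below 0 (median -0.21, percentile 0.71), with Rpl11 1.62-fold lower (1.57 to 1.68), Rpl14 1.56-fold lower (1.51 to 1.62) and Rplp0 1.17-fold lower (1.16 to 1.19). The small subunit had 25 of 33 below 0 (median -0.14, percentile 8.80, and 2.49 in TPM and 2.03 in FPKM), and Rps2 stood apart at 1.72-fold higher (1.70 to 1.75). Of 32 splicing factors, 23 were below 0 (median -0.24, percentile 1.96), with Prpf8 1.92-fold lower. The splicing list left the lowest 2.5% of random lists among genes with a mean of 50 CPM or more (percentile 3.74), in TPM (3.73) and in FPKM (3.47), and without matching on expression the proteasome, large subunit and splicing lists stood at percentiles 5.58, 4.60 and 6.30. Translation factors had a median of -0.12 (percentile 14.4), and Eif5 was the 1 of 36 that met the size rule, 2.43-fold higher (2.40 to 2.45).

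Genes for ribosomal RNA processing, the group to which Nop2 belongs, had a median of -0.03 over 78 members, at percentile 48.3. By the size rule 6 were lower and 2 higher. Riok1 was 3.67-fold lower (3.20 to 4.22), Riok2 2.26-fold lower (2.15 to 2.38), Surf6 2.38-fold higher (2.24 to 2.53), and the abundant Npm1 1.49-fold lower (1.47 to 1.51), and Rbm28 was lower with fractional counts. RNA polymerase I genes had a median of -0.15 (percentile 16.9) and 1 of 20 higher, Taf1a, at 2.66-fold higher. Among 12 genes for acetylation and methylation of cytidines in RNA, Nat10 was lower and Nsun2 (2.46-fold, 2.39 to 2.55) and Nsun3 (3.23-fold, 2.64 to 3.98) were higher, while Thumpd1, the adaptor of Nat10, was 1.27-fold lower (1.24 to 1.31). That list's median was 0.11, at percentile 66.6. In the m6A machinery (median -0.23, percentile 7.87), 2 of 20 genes were lower and 1 higher. Mettl14 was 2.40-fold lower (2.07 to 2.79) and Fto 3.58-fold higher (2.95 to 4.37), and Mettl16, with fractional counts, was lower.

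Genes of DNA methylation and chromatin had a median of -0.03, at percentile 42.7, with 4 of 29 higher and 3 lower. Uhrf1 and Dnmt1, which keep DNA methylation through replication, were 4.71-fold (4.29 to 5.18) and 3.04-fold (2.64 to 3.51) lower. Setdb1, a histone methyltransferase, was 8.57-fold lower (7.03 to 10.5), and Tet3, an enzyme that oxidises methylcytosine, 6.78-fold higher (5.40 to 8.60). In the list for G1 and S phase (median -0.22, percentile 5.54), 4 of 28 genes were lower and 1 higher, among them Gins2 at 4.07-fold lower (3.46 to 4.80) and Slbp at 2.27-fold lower (2.18 to 2.37). Ccne2 (6 reads against 957) was also lower and Cdk6 higher, both with fractional counts. In the list for G2 and M phase (median -0.05, percentile 41.8), 4 of 30 were higher and 4 lower, and Aurkb was 3.29-fold lower (3.05 to 3.56) and Wee1 3.07-fold higher (2.59 to 3.65), while Kif11 was lower and Cenpf higher with fractional counts.

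Stress and death genes went both ways. Among p53 targets and apoptosis genes (median 0.23, percentile 94.4), 4 of 29 were higher and 3 lower. The list lay above the central 95% of random lists at a mean of 20 CPM or more (median 0.30, percentile 98.7) and in FPKM (0.31, percentile 97.6). Polk had 0 reads against 546, at least 180-fold lower, Apaf1 was 14.6-fold lower (9.90 to 22.5), and Phlda3 was higher by a log2 ratio of 1.90. In the integrated stress and unfolded protein response (median -0.06, percentile 39.1), 2 of 25 were higher and 2 lower. At a mean of 50 CPM or more, that list's median was -0.31, at percentile 2.03. Herpud1 had 0 reads against 964, at least 318-fold lower, Manf was 3.12-fold lower (2.95 to 3.30) and Hyou1 2.83-fold higher (2.58 to 3.10), and Ddit3 was also higher. Heat shock genes had a median of -0.31 (percentile 2.94) and 3 of 15 lower and 1 higher. The inducible Hspa1b and Hspa1a had 0 reads against 701 and 652, at least 231-fold and 215-fold lower, but their counts are fractional and uncertain. The abundant Hspa8 was 1.24-fold lower, Dnaja1 2.10-fold lower (2.06 to 2.13) and Hspa4 2.35-fold higher (2.25 to 2.45). In the response to double-stranded RNA and interferon (median -0.54, percentile 10.4), 3 of 9 genes were lower and 1 higher. Mavs was 11.5-fold lower and Ifitm2 2.10-fold lower, while Oas1a (1 read against 294) was lower and Oas1g 3.07-fold higher, both with fractional counts and uncertain.

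Among genes of energy metabolism, nuclear genes of oxidative phosphorylation had a median of 0.01 over 51 members (percentile 77.4), none of which met the size rule. The mitochondrial ribosome had a median of -0.09 (percentile 18.9) and 3 of 58 lower and 0 higher, namely Mrps11 at 2.31-fold lower (2.17 to 2.46), Mrps23 and, with fractional counts, Mrpl19. Glycolysis genes had 5 higher and 4 lower of 19 (median 0.04, percentile 62.6). Pfkm had 563 reads against 1, Ldhb was 7.79-fold higher (6.07 to 10.1), and Pdk1 had 526 reads against 0, at least 177-fold higher. The 4 lower members include Slc2a1 (log2 ratio -1.61) and, with fractional counts, Gapdh (-1.45), both named for this list after their values were seen. Aldoa was 1.03-fold higher (1.01 to 1.04). With a mean of 20 CPM or more the glycolysis median was -0.46, at percentile 0.22.

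Maternal oocyte transcripts, which mark RNA inherited from the egg, had 4 of 9 passing members higher and 2 lower, with a median of 0.73 at percentile 98.1. That place depends on the processing: with DESeq2 size factors, under which 8 members pass, the median was 0.41 at percentile 91.7, and with a mean of 20 CPM or more, where 5 pass, it was 0.12 at percentile 71.6. H1f8, the linker histone of the oocyte, had 286 reads against 0 (at least 96.3-fold higher), Zp3 was 6.12-fold higher (4.98 to 7.59), Oas1e 3.30-fold higher (2.98 to 3.65) and Padi6 2.91-fold lower (2.61 to 3.25). The direction depends on low genes: over all 23 members in the table, of which 10 were at 0 in dsNat10, the median with zeros at their bound was -1.25. The list of the 2-cell stage had a median of -0.19 (percentile 19.1) and 1 of 7 higher and 1 lower, with Nelfa 2.17-fold lower (2.04 to 2.31) and Tdpoz2 higher with fractional counts. Of the markers of other cells in the table, 1 of 5 cumulus cell genes passed the filter (Amhr2, 831 reads against 976, 1.16-fold lower), as did 2 of 6 blood or fibroblast genes (Pecam1, 1879 against 1036, 1.83-fold higher, and Cd68, 673 against 880, 1.29-fold lower). Reference genes had a median of -0.02 (percentile 51.9), with 1 of 14 lower (Gapdh, whose counts are fractional), Tfrc 1.69-fold lower (1.64 to 1.74) and Tbp 1.63-fold higher (1.53 to 1.72). The Y-linked genes differed in direction: Kdm5d had 685 reads against 0, Uba1y 0 against 408, Eif2s3y 193 against 640 and Ddx3y 411 against 588 (list median -0.47, percentile 23.1).

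**Figure D4:**
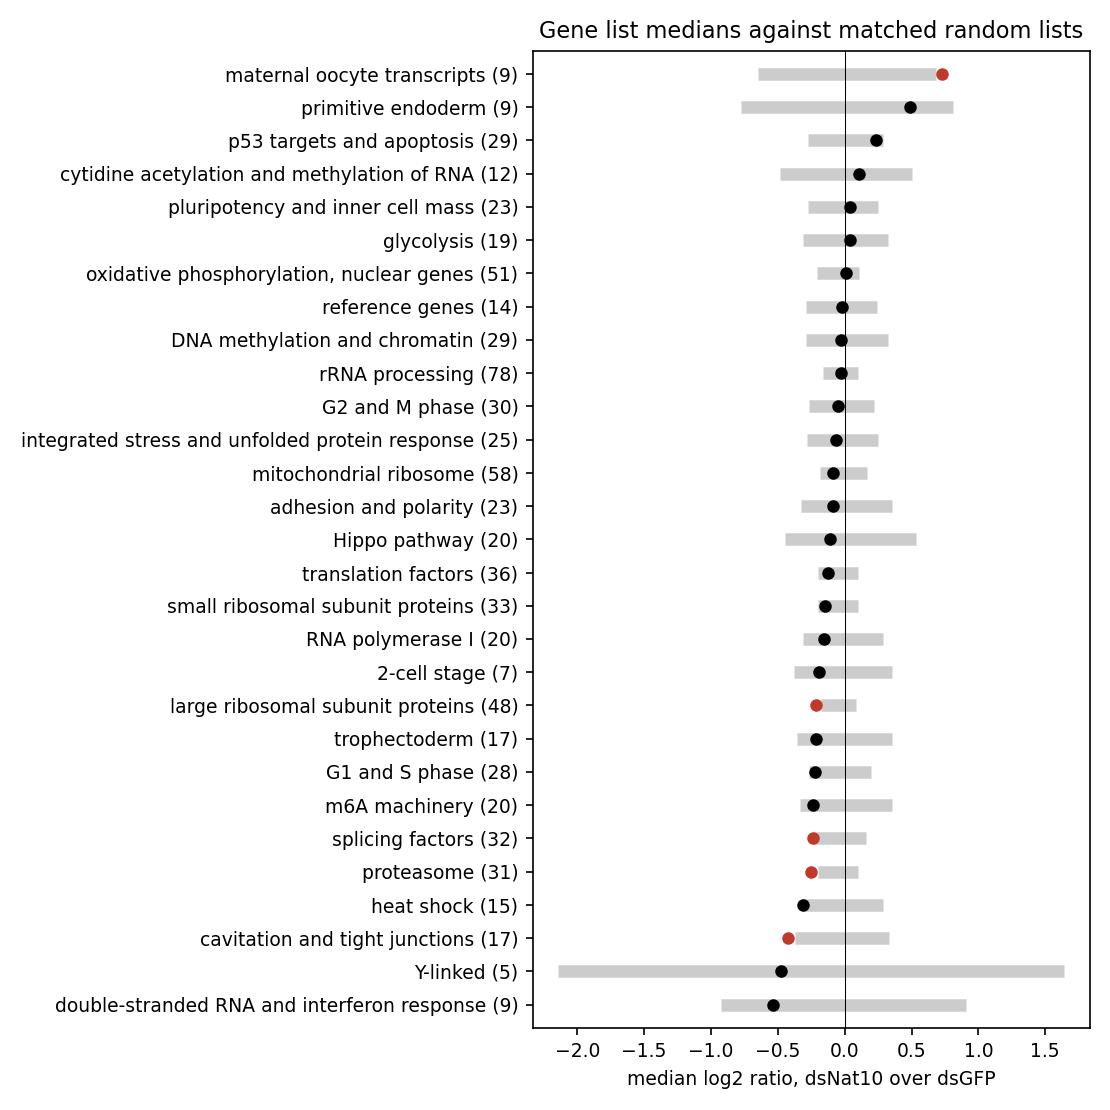
Points give the median log2 ratio of dsNat10 over dsGFP for each of 29 gene lists, grey bars the central 95% of 10000 matched random lists, and numbers in parentheses the members passing the filter. Red points lie outside the bar, 4 below it (proteasome, large ribosomal subunit, splicing factors, cavitation and tight junctions) and 1 above it (maternal oocyte transcripts). Lists of unrelated genes would give 1.45 of 29. That number does not allow for genes of a list varying together or for members shared between lists.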

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

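With plain totals, DESeq2 size factors or totals without the 50 most abundant genes, the share of calls that were higher lay between 49.0% and 52.0% (49.9% as reported). Nat10 stayed lower throughout, but the size of its log2 ratio follows the pseudocount and unit: -3.79 as reported, -4.46 with a pseudocount of 0.1, -2.50 with 5, -3.07 in TPM and -2.77 in FPKM. The ratio of Nop2 was -0.46 in TPM. The number of genes called depends on the limits by construction. Without a filter on the mean 1681 genes were higher and 3252 lower, so that 34.1% of calls were higher. With a mean of 20 CPM or more 524 were higher and 502 lower, and with 50 CPM or more, chosen after seeing the data, 167 and 164. A fold of 1.5 gave 2196 and 2081, and a fold of 4 gave 434 and 686. Chosen after seeing the data, the deposited TPM gave 1009 higher and 836 lower genes, of which 881 and 787 are among those called from counts, FPKM gave 712 and 693, and genes above 0 in both libraries 1228 and 1021. The median of the maternal oocyte list changed sign without a filter on the mean, which adds its members below 5 CPM, to -0.64 at percentile 34.3. It left the highest 2.5% of random lists with DESeq2 size factors (percentile 91.7), a pseudocount of 5 (97.4), a mean of 20 CPM (71.6) or 50 CPM or more (72.4), no matching on expression (97.2) and matching on length (median 0.42, 92.95). Matching on length keeps the 8 members with a known length, and the lower median there comes from the member left out. The cavitation and tight junction list left the lowest 2.5% under 5 alternatives, the splicing list under 4, and the proteasome and large ribosomal subunit lists without matching on expression alone. Across alternatives, 344 list values kept their side of the central 95% of random lists, 17 moved inside it, 10 moved outside it, and 1, the maternal oocyte list without a filter, moved inside with a change of sign. Those that moved outside were glycolysis without a filter (percentile 1.04), at 20 CPM (0.22) and 50 CPM or more (0.555) and in FPKM (0.975), p53 targets and apoptosis at 20 CPM or more (98.7) and in FPKM (97.6), the small ribosomal subunit in TPM (2.49) and FPKM (2.03), heat shock with a pseudocount of 5 (2.45), and the integrated stress response at 50 CPM or more (2.03). Of all these list values 28 had a median of the other sign, in 10 lists, among them primitive endoderm, trophectoderm and glycolysis (-0.46 without a filter). Under 7 other scalings, pseudocounts and units, none of the 158 genes called by the size rule that are named by the rules or belong to a list changed sign, while 4 of 66 named genes within the size limit did, none with a log2 ratio over 0.11 in size. For the 12 highest and 12 lowest genes, 133 values moved by no more than the counting error and 35 moved by more. The error was taken as the distance on the log2 scale from the middle of the interval to its end. It is open for genes at 0, such as Rbsn, so their values could not count as moved by more. With passing genes at 0 set to their bound, the 5 lists outside the random range kept the sign of their median. That outcome was close to fixed, because a gene at 0 keeps its side at its bound. Over all members in the table, the maternal oocyte median was -1.25. Leaving out a replicate was not possible, with 1 library per group, and no paired analysis was possible because each group has a single library. Depth sets the floor of 3 counts, 0.105 CPM in dsNat10 and 0.104 CPM in dsGFP, against which a gene at 0 has only a bound.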

Other observations

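The tests and gene lists in this part were chosen after the values they concern had been seen, except the random lists not matched on expression and the percentile of the Y-linked median, which were planned. The medians of 9 further gene groups lay within the central 95% of matched random lists. The chaperonin and prefoldin genes, which fold newly made actin and tubulin, had a median log2 ratio of -0.21 (14 genes, percentile 7.76). Genes of transport from the endoplasmic reticulum to the Golgi had a median of -0.16 (24 genes, percentile 17.2), cholesterol synthesis -0.15 (21 genes, percentile 18.9), imprinted genes -0.13 (12 genes, percentile 30.6) and the lysosome -0.06 (24 genes, percentile 40.6). Cytosolic aminoacyl-tRNA synthetases stood at -0.03 (20 genes, percentile 53.3), one-carbon and purine synthesis at -0.01 (20 genes, percentile 56.7) and the nuclear pore at 0.11 (25 genes, percentile 80.6). Of the replication-dependent histones only 3 passed the mean filter, with a median of 0.80 at percentile 97.0.

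The first pattern is the excess of genes at 0 in dsNat10, 2657 against 458. Depth is argued against: the dsGFP library thinned at random to the dsNat10 total had 463 genes at 0. Among genes with at least 100 and under 300 reads in dsGFP, 664 were at 0 in dsNat10 and 257 had fewer than 50 reads, a ratio of 2.58 against 0.748 with the libraries exchanged, an all-or-none form that fewer RNA molecules entering the dsNat10 library may give. A loss of low transcripts in the dsNat10 embryos cannot be told apart from this. The summed CPM of those genes had a ratio of 1.21 (bootstrap 95% interval over genes 1.15 to 1.28). That interval leaves out any spread between libraries or embryos. Choosing genes on 1 library also raises the other, as the ratio of 1.46 with the libraries exchanged shows. With 1 library per group, this stays undecided.

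The second pattern is the low median of the proteasome, large ribosomal subunit and splicing lists. Transcript length is argued against as the whole cause, since 3 of the 3 lists stayed in the lowest 2.5% of random lists when these were also matched on length (percentiles 0.765, 2.28 and 1.80). A trend of the ratio across bins of mean CPM is argued against as the whole cause. The lowest median log2 ratio of any bin was -0.053, at 100 to 200 CPM. The list medians were -0.25, -0.21 and -0.24. The highest bin holds all genes at 200 CPM or more (median -0.040), so a trend within it would not show in these values. The percentiles matched on expression do not test a trend with abundance, since the lists were picked against genes of like abundance. The percentiles were 5.58, 4.60 and 6.30 with random lists not matched on expression, and the splicing list stood at 3.74 with a mean of 50 CPM or more, 3.73 in TPM and 3.47 in FPKM, so its place is the least firm of the 3. An effect of the Nat10 knockdown and a difference between these embryo pools both remain open and could not be tested with 1 library per group.

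The third pattern is the disagreement of the Y-linked genes, whose log2 ratios ran from -3.92 to 4.64. The range of 8.56 lay at percentile 96.6 of random lists of the same size and expression, near the upper end of what such lists give. Those lists come from the same 2 libraries and hold every source of difference between them. The percentile therefore cannot single out all-or-none sampling of low transcripts, which remains possible. A different share of male embryos in the pools would move the genes together, so by itself it would not set them apart. Whether such a common shift was also present cannot be told. The median of the 5 passing genes lay at percentile 23.1 of random lists, and the range of single genes is too wide to show or exclude a shift. An effect of the Nat10 knockdown on these genes was not tested.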
